A study of Mus musculus with 4 samples.

How the data were processed

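CTCF, the zinc-finger protein that marks chromatin boundaries and loop anchors, was profiled by chromatin immunoprecipitation and sequencing in whole testes of F1 mice from a cross of the B6 and CAST strains. The series holds 4 samples: 2 immunoprecipitated (IP) samples and 2 input samples. Per the labels' protocols, frozen testes were thawed directly in paraformaldehyde and dissociated, and libraries were made with the KAPA Hyperprep kit. The tissue was not sorted, so the signal of meiotic, postmeiotic and somatic cells could not be told apart.

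The values used were those of 1 deposited CTCF peak list. BWA 0.7.12, MACS2 2.2.7 and the mm10 build are named in the submitters' processing notes, with no role or order given. The list is described as merged, and its peak names carry the words bio2 and merged, so whether 1 or both IP samples entered it was not settled here. The authors deposited, for each peak, a fold enrichment (a ratio at the summit over background), a −log10 p, a −log10 q and a whole-number score. The deposited score was within 1 of 10 times the −log10 q for 100% of the peaks and was not used further. The lowest deposited −log10 q was 1.308, just above the 1.301 that a q threshold of 0.05 leaves, and peak numbers ran from 1 to 51871 without gaps. All fold and −log10 q values are the authors' own and were used only within this list, to describe, rank or filter its peaks and to compare their medians between chromosomes or between gene ends and other places. No value per sample was analysed here, so no replicate check was made, no error between animals can be given, and the read depth is unknown. Intervals on shares cover counting error only.

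Gene positions came from a RefSeq table of the assembly GRCm38.p6, whose chromosome coordinates are those of mm10. The table gave no strand and no genome sequence was used. The plan, written before the data were examined, set promoters as the unit. Because the strand was not in the table, that unit became a window of 1 kb around either annotated end of a protein-coding gene, which mixes transcription start and end sites. The planned tests of the CTCF motif, its share by peak strength, its orientation between neighbours and the matching of genes by CpG content were not run for want of sequence. Genes with a start below 3 Mb on an autosome or X (340 in all, 108 protein-coding) were left out as scaffold coordinates, a choice made after the table was seen, since the first peak on these chromosomes starts at 3009286. This left 21523 protein-coding genes on the 19 autosomes and X. Chromosome length was counted from 3 Mb to the last annotated gene or peak. Coordinates are 1-based.

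Chromosomes, not peaks, were the units of the tests wherever possible. Values on X were compared with the 19 autosomes by an exact two-sided permutation of the X label, whose smallest possible p is 0.05, and values on Y were described only. The share of summits at gene ends was compared with 1000 sets of summits shifted circularly along each chromosome, with a smallest two-sided p of 0.001998. Fold at gene ends was compared with fold elsewhere by an exact two-sided sign-flip test over the log2 ratios of 20 chromosomes, with a smallest p of 1.907e-06. The 14 gene lists, fixed before the data were examined, were each compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, and shares have exact Clopper-Pearson 95% intervals. All 258 names of the symbol lists matched the table. Listed genes that are not protein-coding, such as H19 and Xist, were described and left out of the tests. Fisher's test treats genes as independent, which neighbouring genes of a cluster are not.

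Named genes followed a rule fixed before the data were examined. It took Ctcf and Ctcfl, every gene of the X inactivation list (1 of which is not reported here), 8 imprinted genes, the 3 genes of each other list with the highest fold at a gene-end summit, the 10 peaks of highest fold with their nearest protein-coding gene, and the chromosomes of highest and lowest density. A gene without a gene-end summit was given the distance to its nearest summit. The statistics were tested on simulated data made from the 51630 peaks of the autosomes and X. Among 100 sets without an effect, 4% passed 0.05 for gene ends, 6% for gene lists and 2% for fold at gene ends. In the gene-end sets the mean ratio of observed to shifted summits was 1.002. They thus held no excess from a regional match of peaks and genes, and the gene-end check does not cover that match. All planted genes (100%) were recovered, as was fixed by planting summits within 500 bp of a start and counting within 1 kb. A planted fold ratio of 0.9 was returned as 0.888. The gene-list check used genes drawn at random, so it does not cover lists of neighbouring genes. Alternatives were a stricter peak set (fold or −log10 q of at least 5, or −log10 q at or above the median), windows of 500 bp and 2.5 kb, overlap of the interval in place of the summit, all annotated genes, and mean log2 fold or −log10 q in place of the median fold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.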

Results

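The series title places the work in meiosis, asking how CTCF relates to chromatin loops and the chromosome axis. The deposited list held 51871 CTCF peaks from whole testis, called on IP against background. They covered 33.4 Mb of the mm10 genome, with a median width of 529 bp. The median fold enrichment at the summit was 6.82, from 1.33 to 23.5. A fold of at least 5 was reached by 37292 peaks and a fold of at least 10 by 10164. The values describe 1 merged list, so no spread between replicates stands behind them, and the read depth is unknown.

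The strongest peaks, like most peaks, lay away from the ends of genes. Of the 10 peaks with the highest fold, 9 had their summit over 1 kb from either end of the nearest protein-coding gene. Among all summits of the autosomes and X, only 16.3% lay within 1 kb of such an end. In the fifth with the highest fold the share was 10.9%, against 3.21% after shifting. The highest, with a fold of 23.5 and a −log10 q of 118, spanned chromosome 9 from 48466439 to 48467715, with its summit 1.5 kb from Rexo2, which encodes an RNA exonuclease. The next, with a fold of 22.8, spanned chromosome 9 from 60873158 to 60874163 inside Uaca. Peaks inside Clec16a on chromosome 16 (summit 10565652) and CK137956 on chromosome 4 (summit 127935550) had folds of 22.2 and 21.6. Others lay far from genes. The summit nearest Zfp281 on chromosome 1 (136726326) was 95.9 kb away, with a fold of 22.3. That nearest Usp24 on chromosome 4 (106225681) was 90.3 kb away, also with a fold of 22.3. That nearest Csl on chromosome 10 (99577454) was 180 kb away, with a fold of 22.2. The remaining summits lay 8.64 kb from 1700016K19Rik on chromosome 11 (75991268, fold 22.1), 0.371 kb from Rpl34-ps1 on chromosome 6 (71125372, fold 21.9) and 27.8 kb from Tra2b on chromosome 16 (22293780, fold 21.7). Neighbouring summits on the autosomes and X were a median of 18.1 kb apart, against 32.9 kb for positions drawn at random per chromosome.

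The sex chromosomes carried few CTCF peaks. The X chromosome, which male germ cells silence during meiotic prophase, held 1363 peaks, or 8.12 per Mb. The 19 autosomes held 21.1 ± 4.39 per Mb (SD, n = 19 autosomes), from 15.2 on chromosome 3 to 31.8 on chromosome 11, so X reached 0.384 of the autosomal mean. The exact two-sided permutation p was 0.05, the smallest that 20 chromosomes allow. The Y chromosome held 241 peaks, or 2.65 per Mb. A male also carries a single X, and the read depth of X was not known. How much of X or Y could be covered by uniquely placed reads was not examined.

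Peak density followed gene density across the autosomes, with Pearson's r of 0.841 (permutation p = 2e-05, adjusted p = 2e-05) and Spearman's rho of 0.886 (permutation p = 1e-05, the smallest that 100000 permutations give, adjusted p = 1.33e-05). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.860. X had 5.74 protein-coding genes per Mb, close to chromosome 12 with 5.79. The autosomal line gave 16.9 peaks per Mb at that gene density, and X departed from it by −8.75 per Mb, where the lowest autosome departed by −5.37. Counted per 100 protein-coding genes, X had 142 peaks against 251 ± 33.8 on the autosomes (SD, n = 19 autosomes; exact permutation p = 0.05).

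**Figure D1:**
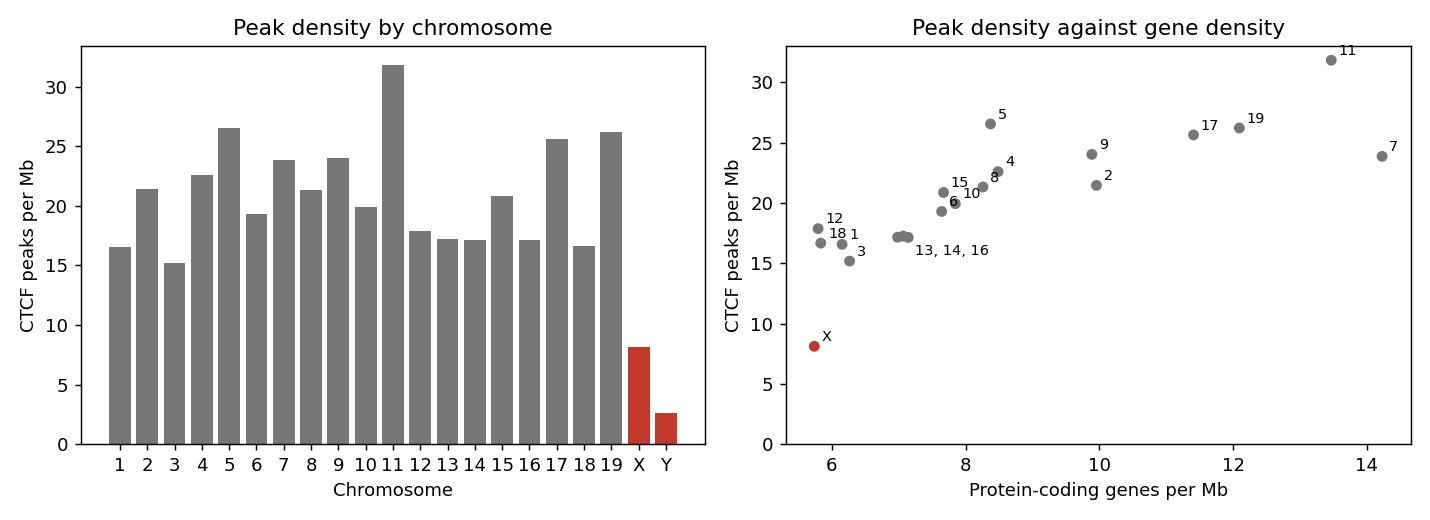
CTCF peaks per Mb on each chromosome (left), and peaks per Mb against protein-coding genes per Mb for the 19 autosomes (grey) and X (red) (right). Each bar or point is 1 chromosome. X, at 8.12 peaks per Mb, lies below every autosome, the lowest of which has 15.2.

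Among called peaks, the median fold on X was 7.18, against 6.83 ± 0.110 on the autosomes (SD, n = 19 autosomes; range 6.59 to 7.01), a ratio of 1.05 with an exact permutation p of 0.05, the smallest possible. This compares only peaks that passed the authors' threshold, and the 5th percentile of fold among them was also higher on X, 3.67 against 3.09 to 3.38 on the autosomes. The −log10 q went the other way, with a median of 21.5 on X against 29.9 ± 1.37 on the autosomes (SD, n = 19; exact permutation p = 0.05). At folds of 6 to 8, a range examined after the values were seen, it was 19.6 on X against 26.5 to 35.7 on the autosomes, so the same fold carried a lower −log10 q on X.

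At the X inactivation centre, the region that carries the silencing RNA Xist and its antisense partner Tsix, 6 peaks lay between the outer ends of Tsix and Ftx (X, 103431517 to 103623754). Their highest fold was 13.4, at a summit inside Tsix at 103441005. A summit 87 bp from an end of Xist had a fold of 12.9. The highest gene-end fold was 10.4 for Tsix, 7.61 for Ftx and 4.94 for Firre, a long noncoding RNA gene. Jpx, Rlim, Cdx4, Chic1 and 4933407K13Rik had no summit within 1 kb of an end. Their nearest summits lay at 9.33, 4.37, 41.6, 15.4 and 9.99 kb. Firre, whose repeats bind CTCF in female somatic cells, had 1 peak inside it, with a fold of 6.01. The list's 4 protein-coding genes, all without such a summit (0 of 4, exact 95% interval up to 60.2%), did not pass the test against other genes (Fisher's exact test, adjusted p = 0.368).

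CTCF summits were concentrated at the ends of genes. Within 1 kb of an annotated end of a protein-coding gene lay 8398 of 51630 summits, or 16.3%. Shifted summits gave 3.20% ± 0.138 (SD, n = 1000 sets), so the observed share was 5.09 times higher (permutation p = 0.001998, two-sided, the smallest possible). A further 42.2% lay inside genes and 41.5% outside, against 39.4% and 57.4% after shifting. Of 21523 protein-coding genes, 8409 (39.1%) had a summit at an end. Both ends had a summit within 1 kb in 886 of these genes, which in a short gene can be the same summit. A larger window lowered the ratio, to 3.38 at 2.5 kb, and all annotated genes lowered it to 3.32. Shifting along whole chromosomes also breaks the regional match of peaks and genes. Windows of the Hox and protocadherin cluster lengths held more peaks on average when centred on genes than when placed at random. The ratio therefore mixes this regional match with any preference for gene ends, and the share of each was not separated.

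Peaks at gene ends were weaker than the others. Their median fold was 5.56, against 7.06 elsewhere, a ratio of 0.788 that was below 1 in 20 of 20 chromosomes (mean log2 ratio −0.33 ± 0.10, SD, n = 20; exact sign-flip p = 1.907e-06, the smallest possible). Restricted to fold at least 5 or to −log10 q at or above the median, the ratio was 0.945 or 0.928, which removing the peaks of low fold moves towards 1 by construction. By strength, 27.1% of the fifth of peaks with the lowest fold lay at gene ends, falling through 17.6%, 13.7% and 12.2% to 10.9% of the fifth with the highest fold. The corresponding ratios to shifted summits were 8.40, 5.51, 4.26, 3.80 and 3.39.

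**Figure D2:**
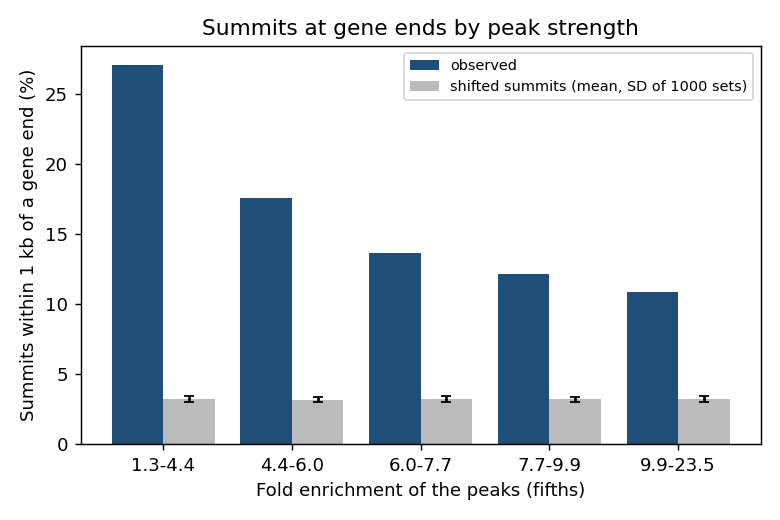
Share of summits within 1 kb of an annotated end of a protein-coding gene, in 5 equal groups of peaks by fold enrichment, for observed summits (blue) and for shifted summits (grey, mean and SD of 1000 sets). The observed share falls from 27.1% to 10.9% while the shifted share stays near 3.20%.

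The clustered protocadherins, cell-surface adhesion genes that neurons express in varying combinations, had the highest share of bound ends among the 14 lists. A gene-end summit was found for 55 of 57 (96.5%, exact 95% interval 87.9 to 99.6), against 38.9% of other protein-coding genes (Fisher's exact test, adjusted p = 9.08e-20). The highest folds were 14.3 at Pcdha7, 13.1 at Pcdhb17 and 12.8 at Pcdhb2, all on chromosome 18, and the other 52 genes ranged from 3.57 to 12.8. Members of this list are neighbours, and the annotated ends of the Pcdhg genes nearly coincide, 399 to 409 bp from 1 summit. Most Pcdhg genes took their highest gene-end fold, 11.9, from that summit. Annotated starts, here the lower coordinate of each gene since the strand was not used, were therefore also examined, a choice made after the values were seen. A summit lay within 1 kb of the annotated start of 53 of the 57 genes, against 21.4% of other protein-coding genes. The 53 genes had 53 distinct summits at a median of 85 bp, with folds from 3.35 to 14.3. By cluster, the median distance was 432 bp for Pcdha, 74 bp for Pcdhb and 78 bp for Pcdhg. The 53 genes comprised 13 of 14 Pcdha, 21 of 22 Pcdhb and 19 of 21 Pcdhg genes. The exceptions were Pcdhac2, Pcdhb1, Pcdhgc4 and Pcdhgc5, whose nearest summits to the start were 53.7, 29.8, 6.11 and 10.6 kb away.

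**Figure D3:**
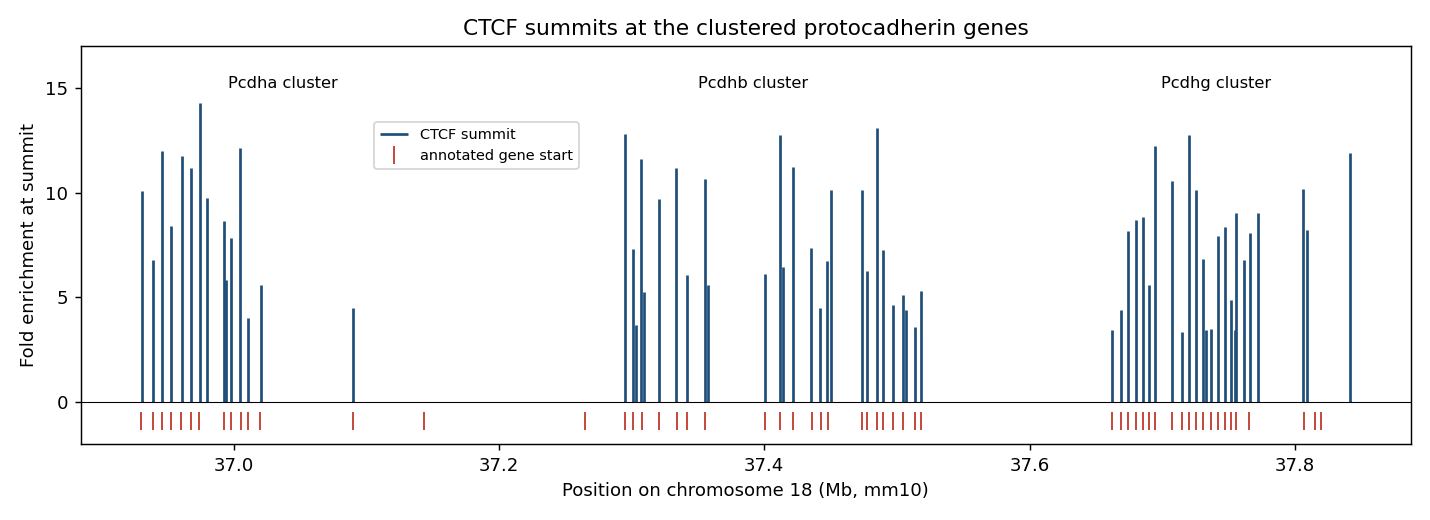
CTCF summits at the clustered protocadherin genes on chromosome 18. The x axis is the mm10 position in Mb. Each blue line is 1 summit, its height the authors' fold enrichment, and each red mark is an annotated gene start (lower coordinate). A summit lies within 1 kb of 53 of the 57 starts.

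Apart from the X inactivation list (0 of 4), the olfactory and vomeronasal receptor genes had the lowest shares. Whether reads could be placed uniquely at such similar genes was not examined. Nor was it examined whether their annotated ends reach the transcription start, so a missing summit need not mean missing binding. Of 1109 olfactory receptor genes, 18 had a gene-end summit (1.62%, exact 95% interval 0.965 to 2.55; exact adjusted p = 3.22e-210). Of 350 vomeronasal receptor genes, 3 did (0.857%, interval 0.177 to 2.48; exact adjusted p = 1.48e-69). The exceptions with the highest fold were Olfr750 with 11.4, Olfr1373 with 10.2 and Olfr159 with 9.01, and the 3 vomeronasal genes were Vmn1r20 with 8.25, Vmn1r27 with 5.61 and Vmn2r29 with 2.501. Liver genes, taken as a tissue not sampled, also had fewer bound ends than other genes (3 of 25, 12%, interval 2.55 to 31.2; exact adjusted p = 0.0221). The bound liver genes were the apolipoprotein genes Apoa2 and Apoa1, with folds of 16.5 and 12.6, and the gluconeogenic gene Pck1, with 6.33. That difference was lost among peaks of fold at least 5 (exact adjusted p = 0.557) and among peaks at or above the median −log10 q (exact adjusted p = 0.931).

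None of the 5 lists of meiotic, germ cell or testis somatic genes passed the test against other genes. Among genes of the meiotic axis and cohesin, 12 of 27 had a gene-end summit (44.4%, exact adjusted p = 0.649). The highest folds were 13.6 at Rec114, whose product is needed for meiotic double-strand breaks, and 10.004 and 9.95 at the cohesin genes Stag2 and Smc3. The other 9 bound genes ranged from 3.93 to 9.08. Among recombination genes, 13 of 25 were bound (52.0%, exact adjusted p = 0.383), with folds of 14.5 at Zcwpw1, a reader of histone marks left by PRDM9, 10.5 at Psmc3ip and 6.29 at Msh5. The other 10 were at most at 5.99. Of 20 genes of spermatogonia and meiotic entry, 9 were bound (45.0%, exact adjusted p = 0.649), led by Zbtb16 (7.29), Foxo1 (7.22) and Kit (7.08), with the other 6 between 4.51 and 6.98. Of 25 spermatid genes, 8 were bound (32.0%, exact adjusted p = 0.649), led by Catsper2, part of the sperm calcium channel, with 11.2, Tssk6 with 9.97 and Crem with 8.58. The other 5 ranged from 2.75 to 5.67. Of 20 Sertoli and Leydig cell genes, 6 were bound (30.0%, exact adjusted p = 0.649), led by Amh, encoding anti-Müllerian hormone, with 12.3, Nr5a1 with 9.86 and Clu with 8.94. The other 3 ranged from 3.80 to 7.42.

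Housekeeping genes were bound at 15 of 29 (51.7%, exact adjusted p = 0.368), led by Gapdh with 12.9, Rpl13a with 10.2 and Chmp2a with 9.35, and the other 12 were at most at 7.88. Genes for CTCF and its cofactors were bound at 7 of 10 (70%, interval 34.8 to 93.3, exact adjusted p = 0.154), led by Zfp143 with 10.2 and Adnp with 8.74. At Ctcf itself (chromosome 8, 105636474 to 105682922), a summit of fold 8.52 lay 388 bp from an end. At Ctcfl, the testis-expressed paralog (chromosome 2, 173093609 to 173119525), a summit of fold 7.48 lay 271 bp from an end. This list passed the threshold among peaks of fold at least 5 (exact adjusted p = 0.00887) and with a 500 bp window (exact adjusted p = 0.0391). These intervals are wide, so modest differences of the short lists were not detectable.

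**Figure D4:**
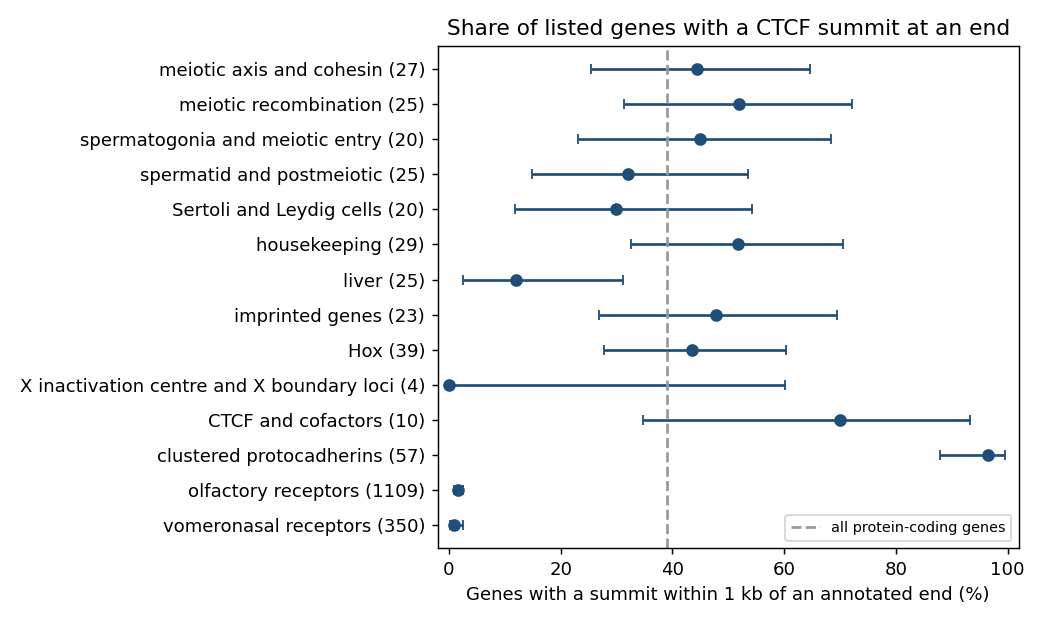
Share of the protein-coding genes of each list (number in brackets) with a CTCF summit within 1 kb of an annotated end. Points are shares, bars exact 95% intervals, and the dashed line marks 39.1%, the share of all protein-coding genes. Protocadherins lie at 96.5%, olfactory receptors at 1.62% and vomeronasal receptors at 0.857%.

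Imprinted genes, expressed from 1 parental allele, had a gene-end summit at 11 of 23 protein-coding members (47.8%, exact adjusted p = 0.621). Between H19 and Igf2 on chromosome 7 lay 3 peaks. Their summits were at 142580715, 142581896 and 142610743, with folds of 4.61, 13.4 and 10.3. The pair nearer to H19 lay 2.57 kb from it and beyond, on the side of its imprinting control region, a CTCF-dependent insulator in somatic cells. Igf2 had its nearest summit 4.44 kb from an end. Of the 8 imprinted genes chosen beforehand, Rasgrf1, Kcnq1ot1 and Peg3 had a gene-end summit, with folds of 10.1, 7.35 and 3.53. Higher folds in this list, 15.6 at Magel2 and 15.5 at Peg13, were picked out after the values were seen. Meg3, Mest and Grb10 had their nearest summits 2.04, 3.64 and 11.6 kb from an end, with folds of 6.10, 8.60 and 7.01. A summit inside Grb10 had a fold of 14.5.

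The Hox genes, which pattern the body axis, had a gene-end summit at 17 of 39 genes (43.6%, exact adjusted p = 0.649), led by Hoxd10 with 10.4, Hoxd11 with 10.2 and Hoxa10 with 9.81, with the other 14 between 3.13 and 8.30. With a 2.5 kb window this list passed the threshold (exact adjusted p = 0.0102). The Hoxa cluster (chromosome 6, 52155367 to 52260880) held 17 peaks, Hoxb (chromosome 11, 96194316 to 96368254) 16, Hoxc (chromosome 15, 102921131 to 103036856) 10 and Hoxd (chromosome 2, 74668225 to 74765142) 15. The highest fold was 15.4 in Hoxb, 10.4 in Hoxd, 10.1 in Hoxa and 7.85 in Hoxc.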

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

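The choices per 100 genes, X without its last 1 Mb, matching by local gene density, leaving out X and Y, and leaving out olfactory and vomeronasal receptors from the other genes were added after the data were seen. Of the 30 alternatives of the main results, 28 kept direction, side of the threshold or, for counts, stayed within 1.5 times; for the X comparisons only the direction could change, since their p cannot fall below 0.05. The X to autosome ratio of 1.05 for median fold became 0.718 with −log10 q in place of fold. At equal fold −log10 q was lower on X than on every autosome in each of 6 ranges of fold, with ratios to the autosomal mean of 0.641 to 0.911, so the measures part there. The count of 4 lists past the threshold became 2 without olfactory and vomeronasal receptors, since those lists are then gone by construction. Among single lists, 83 of the alternatives kept their direction and side, 2 ended the call of liver genes and 3 brought Hox or CTCF cofactor genes past the threshold, each described with its list. The log2 odds ratios of lists that never passed the threshold changed sign for axis and cohesin (−0.042 with fold at least 5), spermatogonia (−0.60 with −log10 q at or above the median), spermatids (0.046 at 2.5 kb), imprinted genes (−0.19 at 2.5 kb) and Sertoli and Leydig genes (0.41 with −log10 q at or above the median, 0.19 with fold at least 5, 0.49 at 2.5 kb). Motif alternatives and lengths without N or masked bases were not run. No paired analysis was possible because the peak list carries no value per sample, and leaving out a replicate was not possible for that reason either. With the depth unknown, how many weak sites were missed cannot be stated.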

Other observations

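The gene types, symbol families, cluster windows and chromosome ends below, and the tests of read depth and of a uniform halving of fold on X, were chosen after the results were seen. Other kinds of gene also had CTCF summits within 1 kb of an end more often than after shifting. Across 10 gene types, the ratio to shifted summits was highest for tRNA genes, with 26.8% of 403 bound against 4.12% ± 1.36 (SD, n = 200 shifted sets). Variable segments of the antigen receptor loci followed protein-coding genes, with 20.9% of 374 against 4.41% ± 1.96, whereas their pseudogene segments had 5.88% of 153 against 4.68% ± 2.56. Long noncoding RNA genes had 19.3% of 12609 against 7.67% ± 0.309. The permutation p was 0.00995, the smallest possible, for tRNA, variable segments and long noncoding RNA (adjusted p = 0.0142), and 0.687 for the pseudogene segments. Ordinary pseudogenes had 5.20% against 5.73% ± 0.277 (permutation, adjusted p = 0.0995). Gene types that lie next to protein-coding genes share their summits, which was not separated here.

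Among 149 families of at least 15 protein-coding genes sharing a symbol stem, olfactory and vomeronasal receptors left out, 23 had a higher and 32 a lower share of bound ends than other genes (Fisher's exact test, adjusted over the families). Matching on local gene density kept 22 and 32 of them past the threshold. The lower families included keratin-associated proteins (Krtap, 1 of 56, exact adjusted p = 6.22e-10), Pramel genes (2 of 46, adjusted p = 7.48e-07), cytochromes P450 (Cyp, 15 of 99, adjusted p = 7.48e-07), secretoglobins (Scgb, 2 of 40), alpha-defensins (Defa, 0 of 28) and prolactin relatives (Prl, 0 of 25). The X-linked homeobox genes named Rhox had 2 of 33 (exact adjusted p = 0.00012). They were not compared with other genes of X, which had fewer peaks per 100 genes than any autosome. The higher families included Integrator subunits (Ints, 14 of 15, exact adjusted p = 0.000482), Zbtb zinc-finger genes (29 of 41, adjusted p = 0.00171), Cep centrosomal genes (27 of 38) and Dhx helicases (14 of 16). Tandem families are not independent genes, and whether reads could be placed uniquely in them was not examined.

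Against 10000 random autosomal windows of its length, as many peaks as in Hoxa (17) were found in 0, as in Hoxd (15) in 5, as in Hoxb (16) in 171 and as in Hoxc (10) in 293. Against windows centred on genes, the numbers were 45, 71, 783 and 1302. For the protocadherin clusters the gene-centred windows with as many peaks numbered 55 for Pcdhg (24 peaks), 230 for Pcdhb (27 peaks) and 2604 for Pcdha (15 peaks). The last 1 Mb of Y with annotation or peaks held 34 peaks, against 207 on the rest of Y. At folds of 4 to 5, the 7 peaks of that end had a median −log10 q of 27.7, against 8.47 for autosomal peaks.

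X had fewer peaks per Mb than any autosome. A single X copy that lowers the signal could contribute, and its planned test decided nothing: X peaks of fold at least 5 numbered 6.11 per Mb, inside the range of 2.72 to 6.34 for autosomal peaks of fold at least 10, but the drop of the upper folds that was also required was not seen. A uniform halving of fold was argued against by the 95th percentile of fold, 15.1 on X against 12.92 to 13.99 on the autosomes, and lower gene density as the whole cause by the 142 peaks per 100 genes, under the lowest autosome with 168. Loss of weak peaks through lower read depth on the single X, with fold unchanged, stays open as all or a part of the cause. As it would need, −log10 q at equal fold was lower on X than on every autosome in 6 of 6 ranges of fold (ratios 0.641 to 0.911). The 5th percentile of fold was also higher, 3.67 on X against 3.09 to 3.38. Lower depth as the whole cause was argued against by peaks of fold at least 10. They numbered 1.95 per Mb on X, under the lowest autosome with 2.72 (exact permutation p = 0.1, adjusted p = 0.117). On X their −log10 q was at least 33.7, far above the authors' threshold, so lower depth alone should not remove such peaks. At fold at least 15 this was not seen: the X to autosome ratio was 0.781, with 2 autosomes below X (exact permutation p = 0.35). Gene density and depth together stay open. Peaks of fold at least 10 per 100 genes numbered 34.1 on X, inside the autosomal range of 33.8 to 64.6 (exact permutation p = 0.15). Only chromosome 7 lay below X, and the next lowest, chromosome 19, had 41.4. The silencing of X in meiosis was not tested.

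Summits at gene ends exceeded shifted summits, and weak enrichment of open chromatin in the pull-down could add such peaks. The planned test assumed that such peaks would be weak. In it, the fifth of peaks with the highest fold still had a ratio of 3.39, above the 1.21 of the highest shifted set. Weak peaks alone therefore did not make up the excess. The test cannot exclude open chromatin as the cause, since such signal may also reach strong peaks. Shifting also breaks the regional match of peaks and genes, which raises the ratio at any strength. Open chromatin stays open in particular for the weaker peaks, since the ratio was 8.40 in the fifth with the lowest fold. No biological explanation was tested.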
